A study of Mus musculus with 21 samples.

How the data were processed

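Messenger RNA was sequenced from the cecum of C57BL/6 mice, a common inbred strain, kept on a Total Western Diet, a rodent diet built to match the nutrient intake of a typical American diet. Per the labels, the diet held 0%, 0.5%, 1.0% or 2.5% broccoli powder. Total RNA was extracted with Tri-Reagent and spin columns, and strand-marking mRNA libraries were made by adapter ligation and pooled in equal molar amounts, per the labels' protocols. The authors deposited 1 table of raw counts per gene for all 21 libraries, and the submitters' processing notes name the genome build mm10. The aligner, the counting tool, the annotation release and the strand setting of the counting are not given in the sources used here. All values of the deposited count table were whole numbers, and all 21 columns of per-sample values matched a sample by name.

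The table listed 25361 gene identifiers, of which 5881 had a count of 0 in all libraries. Names and coordinates were taken from GENCODE mouse release 21, on GRCm38 (mm10), in which 25268 identifiers were found and 93 were not. Of these, 21432 were protein coding. Groups were taken from the diet in the labels, with 6 libraries at 0% and 5 at each other dose. Replicate numbers were given in accession order, so they name a library and pair nothing. The labels number the animals, so libraries were taken to be separate mice. Apart from the 3 animals numbered above 70, the numbers ran in blocks by diet. They were 8 to 17 at 0%, 18 to 26 at 0.5%, 31 to 37 at 1.0% and 40 to 46 at 2.5%. No cage is named in the labels used, so mice were treated as independent, and a difference that follows the numbering cannot be told from diet. Libraries of 1 diet were checked for duplicates with a chi-square test of their counts over genes with a summed count of at least 20. The lowest chi-square per degree of freedom was 17.1, so no pair agreed within sampling noise.

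Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr by diet, and the robust quasi-likelihood test, in 1 fit of all 21 libraries. The filter kept 15652 genes. The contrasts were each dose against 0%, the equal-weight mean of the 3 doses against 0%, the slope of log2 expression per 1% broccoli powder, any difference among the 4 diets, and any difference among the 3 broccoli diets. Every adjusted p for a gene is from this test with Benjamini-Hochberg adjustment over the genes tested, unless another tool is named, and a gene was called at an adjusted p under 0.05. All tests were two-sided. Fold changes are given as log2 values with their standard error, CPM values are counts scaled by the library totals with their TMM factors, and levels are means ± SD.

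Gene lists for pathways, cell types and signs of RNA quality were written before the data were examined. Of 37 lists, 35 were tested with limma 3.58.1 camera on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists. The mean change of a list is taken from log2 CPM, and the signs of its members from the gene test, so these can differ. Of the others, 1 had fewer than 3 tested genes and 1 served only to check labels. The camera test was repeated with a correlation estimated from each list, and fry, which asks whether the genes of a list move on balance one way, was run beside it. For 16 lists of other cell types or RNA quality, the mean log2 CPM per library was compared between each dose and 0% by an exact permutation test over all 462 splits of the 6 and 5 libraries, which made 48 tests adjusted together. For each called list, the libraries on broccoli whose list mean lay beyond all 6 controls were counted after the calls were seen. The first principal component was taken from log2 CPM of the tested genes, centred per gene.

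The genes named were chosen by a rule fixed before the data were examined. Per comparison they were the 12 largest increases and 12 largest decreases among called genes with a mean of at least 1 CPM in a group, and up to 4 called members of each list. Where fewer than 10 genes passed, the 5 lowest unadjusted p in each direction with at least 1 CPM were added as values that did not pass. In every comparison 17 anchor genes were to be named whatever their p, of which 1 is not reported here. For the 2 tests among diets they were the 10 lowest p. Predicted genes, clones and antigen receptor segments were counted but not named, except in the 2 tests among diets. Genes named outside the rule, such as list members that passed when adjusted over the list alone and Wee1, were chosen after their values were seen. Cxcl16 and Mdm2 were named by the rule for the test among the 3 broccoli diets, but their values per library were picked out after being seen.

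Fold changes of the 3 doses share the 6 control libraries, so their correlation was set beside 20 simulations and 20 splits of the controls, 3 against 3. In each simulation all 21 libraries, controls included, were redrawn independently from 1 mean per gene, and the simulated doses shared the simulated controls. The alternatives planned were RLE scaling (the DESeq2 size factors), library totals, no filter, a filter of 1 CPM in 5 libraries, DESeq2 1.42.0, limma voom with quality weights, estimation without the robust option, 1 surrogate variable from sva 3.50.0, smooth muscle and B cell list means as covariates, fits of 2 groups only, dose as a rank, leaving out the 3 animals numbered above 70, and leaving out each library in turn. Chosen after the data were seen were covariates for the small intestine and adipose lists and a fit without 6 libraries whose small intestine list mean was above 3. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

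The gene test was tested on simulated counts drawn for the 15652 genes from the real means and library sizes, with 200 genes changed. In the simulation of 2.5% against 0%, 52.2% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 97.0% of those changed 4-fold were recovered, and 4.4% of calls were false. The share of false calls was 14.1% for DESeq2 and 3.2% for voom. The counts were drawn independently for each gene and library, without correlation between genes or shared differences in tissue make-up. These rates therefore may not hold for the real libraries. Library totals ran from 28514263 to 58594569 counts, so 1 CPM before scaling stands for 28.5 to 58.6 counts, and genes near that level carry sizeable counting error. Sequence-level measures such as GC bias were not analysed here.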

Results

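Gene expression was measured by RNA sequencing in the cecum, the pouch at the start of the large intestine where gut microbes ferment plant material. Mice of 3 weeks of age were kept on a Western-type diet for 6 weeks and were then given the same diet with 0%, 0.5%, 1.0% or 2.5% broccoli powder for 3 more weeks. Broccoli holds glucosinolates, whose breakdown products include ligands of the aryl hydrocarbon receptor and activators of NRF2. The series asks how dietary broccoli relates to the gut microbes and to gene expression of host and bacteria. The host cecum is what is analysed here, in 6 mice at 0% and 5 at each other dose.

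Library totals ran from 28514263 (replicate 6) to 42687431 counts at 0%, from 35057688 to 50757142 at 0.5%, from 37327202 to 58594569 (replicate 5) at 1.0% and from 33132637 to 39675518 at 2.5%. Mitochondrially encoded transcripts took between 22.1% and 31.8% of the counts of a library.

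Markers of the small intestine and its Paneth cells differed far more between mice than between diets. The list of these markers includes Fabp6, the ileal bile acid binding protein, Apoa1, an apolipoprotein made by enterocytes of the small intestine, and the Paneth cell defensin Defa24. Its mean log2 CPM was 5.09 in 0% replicate 5, 5.51 in 1.0% replicate 1, 3.79 in 0.5% replicate 4, 3.19 in 0.5% replicate 1, and 3.24 and 3.17 in 2.5% replicates 1 and 2. The other 15 libraries lay between 0.46 and 1.70. Group means were 1.71 ± 1.69 (SD, n = 6) at 0%, 2.15 ± 1.26 (n = 5) at 0.5%, 1.88 ± 2.07 (n = 5) at 1.0% and 1.89 ± 1.21 (n = 5) at 2.5%. Apoa1 stood at 317 CPM in 0% replicate 5 and 323 CPM in 1.0% replicate 1, and Fabp6 at 63.3 and 71.7 CPM in the same libraries.

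**Figure D1:**
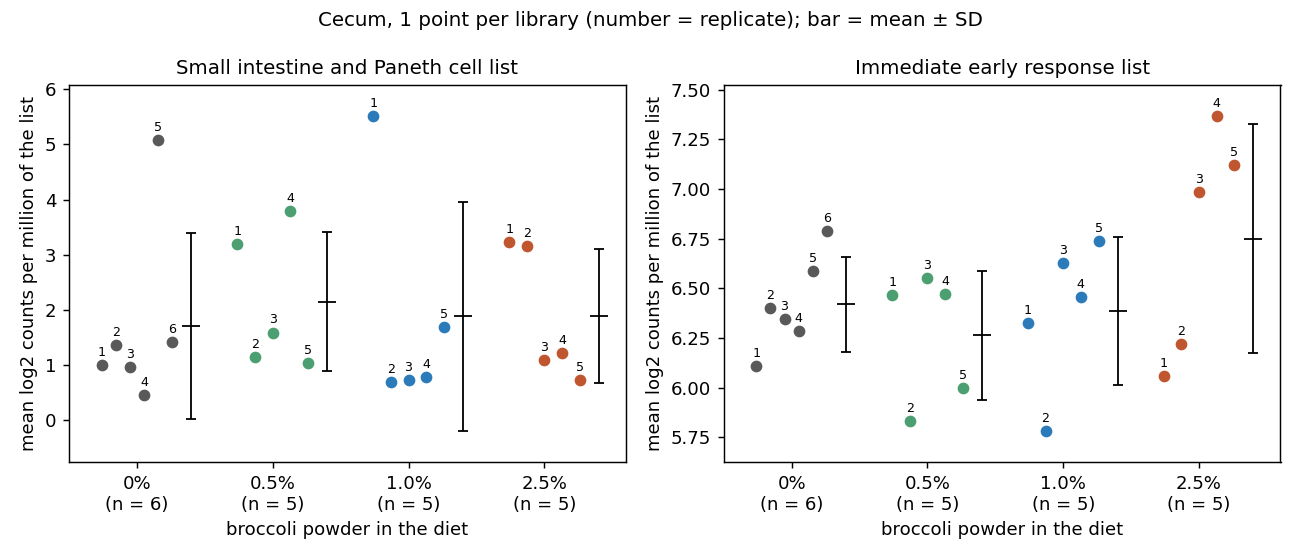
Mean log2 CPM of the small intestine and Paneth cell list and of the immediate early response list in each of the 21 libraries, by diet; points are libraries numbered by replicate, and bars show the mean ± SD. The small intestine list exceeded 3 in 6 libraries spread over all 4 diets, and the immediate early list was highest in 2.5% replicates 3, 4 and 5.

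The diet with 2.5% broccoli powder was compared with 0% to ask what the highest dose did to the cecum. Ahrr, the repressor of the aryl hydrocarbon receptor and itself a target of that receptor, rose from 2.19 ± 0.52 CPM (SD, n = 6) to 4.42 ± 1.06 (n = 5), a log2 change of 1.01 ± 0.20 (SE). Cyp2c23, a cytochrome P450 that makes epoxides of arachidonic acid, rose from 1.14 ± 0.15 to 2.51 ± 0.41 CPM. Edn3, the peptide endothelin 3, rose from 27.5 ± 2.88 to 41.0 ± 3.78 CPM, and the paired-box transcription factor Pax8 from 8.20 ± 1.19 to 13.5 ± 1.51 CPM. Spp1, which encodes the secreted phosphoprotein osteopontin, fell to 0.297 of its control level, from 1.23 ± 0.34 to 0.36 ± 0.10 CPM.

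In all, 17 genes were called at 2.5%, 15 of them higher and 2 lower, or 5 and 2 with library totals as the scaling. In log2 terms Cyp2c23 changed by 1.14 ± 0.22 (adjusted p = 0.0441), Pax8 by 0.72 ± 0.11 (adjusted p = 0.0167) and Edn3 by 0.58 ± 0.10 (adjusted p = 0.0167). Ahrr had an adjusted p of 0.0444, and Spp1 changed by -1.75 ± 0.29 (adjusted p = 0.0167). Adprm, a hydrolase of ADP-ribose and CDP-alcohols, rose by 0.55 ± 0.10 (adjusted p = 0.0249), and Crym, a thyroid hormone binding protein, by 0.54 ± 0.11 (adjusted p = 0.0444). The zinc finger gene Zfp395 fell from 29.1 ± 3.34 to 20.9 ± 2.21 CPM, a log2 change of -0.48 ± 0.09 (adjusted p = 0.0441). In each of these 8 genes, 5 of 5 libraries at 2.5% lay beyond all 6 control libraries. On GRCm38, Ahrr lies on chromosome 13 from 74211118 to 74292331 (minus strand), Pax8 on chromosome 2 from 24420560 to 24475599 (minus), Edn3 on chromosome 2 from 174760619 to 174784042 (plus), Zfp395 on chromosome 14 from 65358389 to 65398930 (plus) and Spp1 on chromosome 5 from 104435118 to 104441050 (plus). Spp1 overlaps the predicted gene Gm42793, Pax8 lies opposite Gm13415 and Zfp395 opposite Gm48449, and since the strand setting of the counting is not given, counts of these genes are uncertain to that extent.

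**Figure D2:**
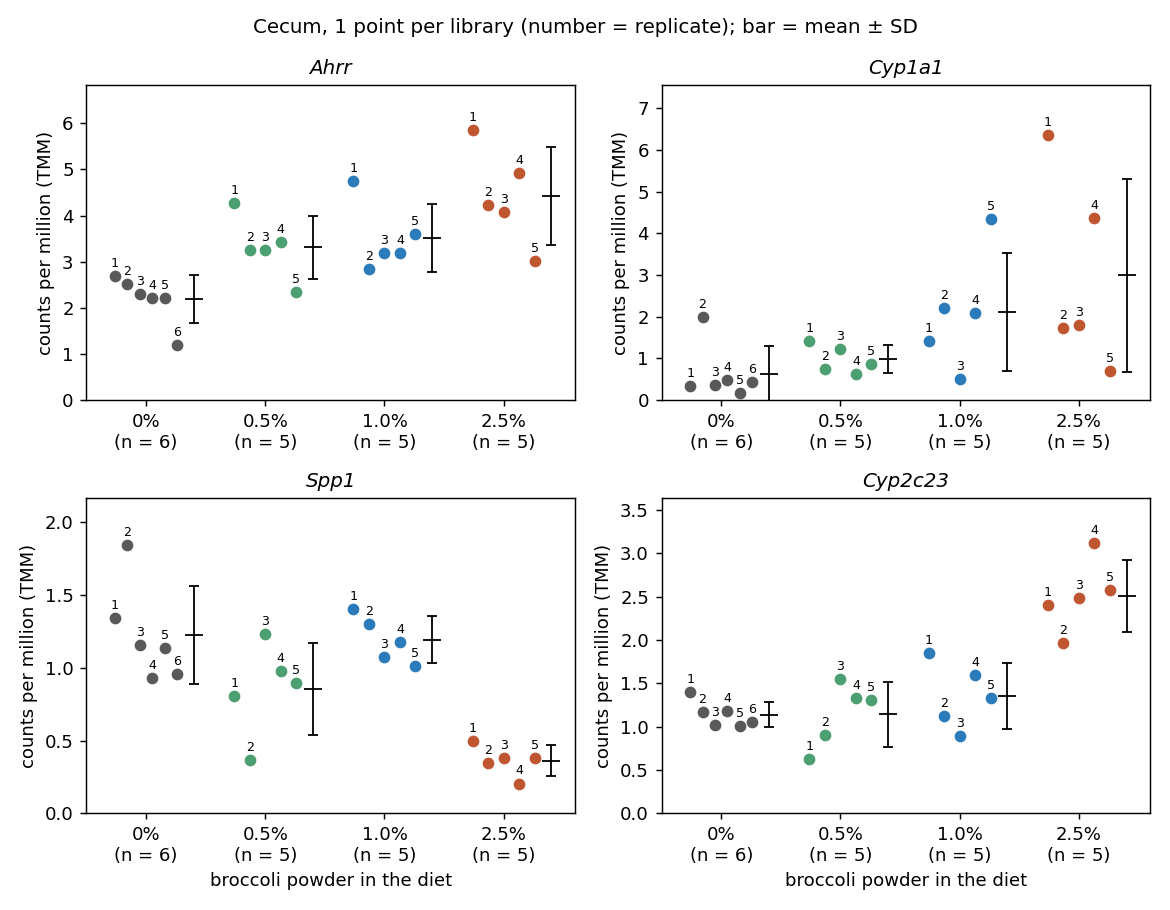
CPM of Ahrr, Cyp1a1, Spp1 and Cyp2c23 in each library, by diet; points are libraries numbered by replicate and bars show the mean ± SD, with any part below 0 hidden. All 5 libraries at 2.5% lay above the 6 controls for Ahrr and Cyp2c23 and below them for Spp1, while 2 of 5 did for Cyp1a1.

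A further 6 named genes rose at 2.5% on average. They were the linker histone Hist1h1e (1.94 ± 0.32, adjusted p = 0.0167), the adhesion gene Ceacam16 (2.32 ± 0.46, adjusted p = 0.0444), Ly6g6c of the Ly6 family (1.33 ± 0.24, adjusted p = 0.0441), the Ras exchange factor Rasgef1b (0.91 ± 0.17, adjusted p = 0.0441), the small GTPase Rhou (0.60 ± 0.12, adjusted p = 0.0444) and the chromatin protein Hmga1b (0.59 ± 0.12, adjusted p = 0.0479). Their increase lay mostly in replicates 3, 4 and 5. Hist1h1e was at 11.2, 8.17 and 6.97 CPM there, at 2.67 and 2.69 CPM in replicates 1 and 2, and at 1.66 ± 0.43 CPM (SD, n = 6) at 0%. Ceacam16 was at 3.04, 2.39 and 2.28 CPM in replicates 3 to 5 and at 0.47 and 0.43 CPM in replicates 1 and 2, so 3 of 5 libraries lay beyond all controls. For Rhou and Hmga1b 4 of 5 did, and for Hist1h1e, Ly6g6c and Rasgef1b 5 of 5. Counts of Hist1h1e (overlapping Hist1h2be), Ceacam16 (opposite Gm19345), Ly6g6c (opposite Mpig6b), Rhou (overlapping Gm20388), Rasgef1b (several overlapping genes) and Hmga1b (a near copy of Hmga1) are uncertain, because reads may have been shared. The other 3 called genes were Wee1 (0.48 ± 0.10) and 2 predicted genes.

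The 17 calls compare with 77 by DESeq2, which included all 17, and 9 by limma voom, and 1319 genes had an unadjusted p under 0.05. The count was 0 in a fit of the 2 groups only, 5 without animals numbered above 70 and 6 with a surrogate variable, but 17 with RLE scaling and 21 with smooth muscle and B cell covariates. No gene was called without 2.5% replicate 3, 4 or 5, while 56 were called without 2.5% replicate 1, 53 without 2.5% replicate 2, 22 without 0% replicate 1, 12 without 0.5% replicate 1, and 2 to 9 without any 1 of the other libraries. Without the 6 libraries high in small intestine markers 121 were called, 16 of the 17 among them, but that fit also leaves out 2.5% replicates 1 and 2 and so rests on replicates 3, 4 and 5.

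**Figure D3:**
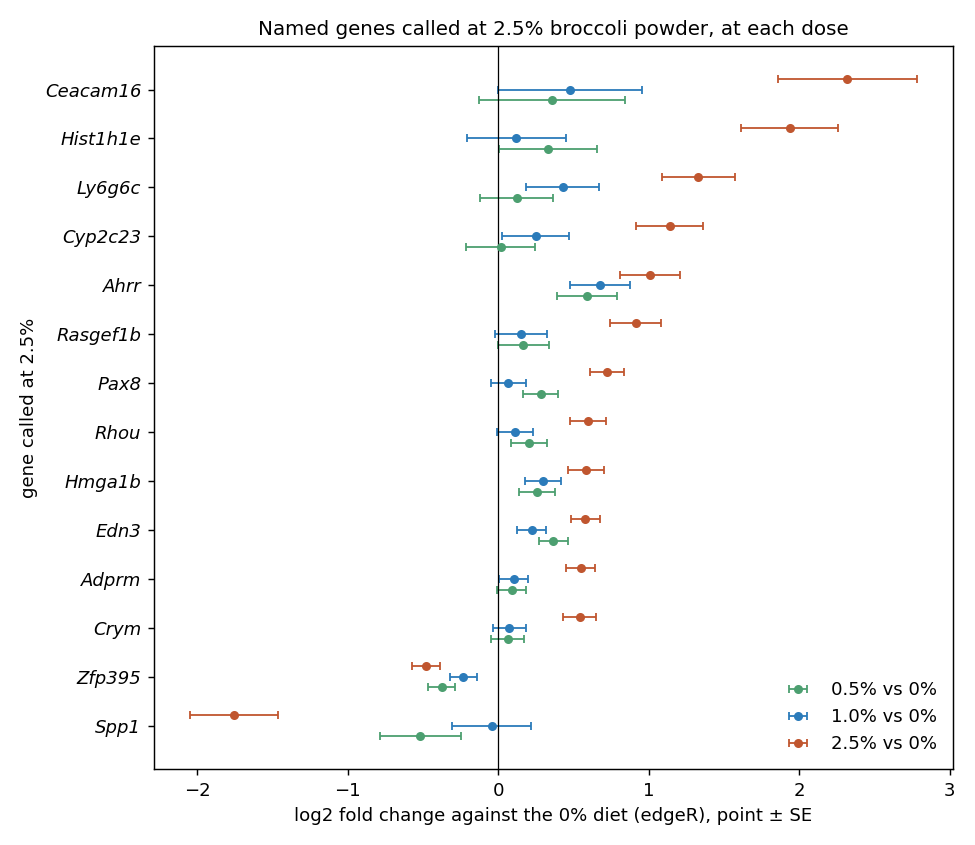
Log2 fold change against 0% ± SE at 0.5%, 1.0% and 2.5% broccoli powder (n = 5 each, against n = 6) for the 14 named genes called at 2.5%. All 12 higher genes and both lower genes were called at 2.5%, and none of them at 0.5% or 1.0%.

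Targets of the aryl hydrocarbon receptor were higher at 2.5% as a list, with 7 of 8 measured members positive, a mean log2 change of 0.56 and a median of 0.28. The camera test gave an adjusted p of 0.000499, and an adjusted p = 0.0877 with an estimated correlation. Ahrr was the 1 member called over all genes, while 4 passed when adjusted over the list alone. The others were Cyp1a1, the cytochrome P450 that is the classical target of the receptor, Tiparp and Nqo1. Cyp1a1 stood at 0.625 ± 0.674 CPM (SD, n = 6) at 0% and 2.99 ± 2.32 (n = 5) at 2.5%, a log2 change of 2.27 ± 0.61 that did not pass over all genes (adjusted p = 0.231). The list mean lay above all 6 controls in 4 of 5 libraries at 2.5%. Tiparp changed by 0.31 ± 0.12 (adjusted p = 0.490), Nqo1 by 0.27 ± 0.11 (adjusted p = 0.496) and Cyp1b1 by 0.83 ± 0.61 (adjusted p = 0.726).

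Enzymes and transporters of xenobiotic metabolism were called higher at 2.5% (21 of 26 members positive, adjusted p = 0.000499), with Ces1f at 0.48 ± 0.11 passing over the list alone (adjusted p = 0.560 with an estimated correlation for the list). The list mean was 6.19, 6.17 and 6.13 in replicates 1 to 3, and 5.95 and 5.84 in replicates 4 and 5, within the control range of 5.76 to 5.96. Ces1f was at 55.6 and 49.8 CPM in replicates 1 and 2, which were high in small intestine markers, and at 41.8, 43.8 and 35.4 CPM in replicates 3 to 5, while 0% replicate 5, the control highest in those markers, had 28.3 CPM of Ces1f and the lowest list mean of the controls. Colonic ion, water and short-chain fatty acid transport had 20 of 22 members positive (adjusted p = 0.00179, and adjusted p = 0.269 with an estimated correlation). The circadian clock list had 12 of 16 positive (adjusted p = 0.00925, and adjusted p = 0.216 with an estimated correlation). Blood transcripts were called lower, with 1 of 5 positive and Hba-a1 at -0.65 ± 0.20 and Hbb-bs at -0.76 ± 0.19 (adjusted p = 0.00925, and adjusted p = 0.269 with an estimated correlation). MHC class II genes were called lower, with 2 of 10 positive (adjusted p = 0.0122, and adjusted p = 0.656 with an estimated correlation). List means lay beyond all 6 controls in 2 of 5 libraries at 2.5% for colonic transport and the clock, and in 3 of 5 for blood and MHC class II.

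A further 6 lists were called at 2.5%, each with an adjusted p = 0.752 with an estimated correlation. Cholesterol synthesis and uptake had 19 of 20 members positive (adjusted p = 0.000499), with Insig1 at 0.41 ± 0.18 and Sqle at 0.37 ± 0.18, and its list mean was 5.97 and 6.16 in replicates 1 and 2 and 6.31, 6.47 and 6.63 in replicates 3 to 5, against 6.10 ± 0.17 (SD, n = 6) at 0%. Cell proliferation had 19 of 21 positive (adjusted p = 0.00886), with a list mean of 3.30 and 3.64 in replicates 1 and 2 and 4.04, 4.08 and 3.82 in replicates 3 to 5, against 3.64 ± 0.17 (SD, n = 6) at 0%. Tight and adherens junctions had 14 of 20 positive (adjusted p = 0.0146, Tjp1 and Cldn23 passing over the list alone), NRF2 targets 19 of 27 (adjusted p = 0.0423), and enteric neurons and glia 1 of 15 (adjusted p = 0.0194). In replicates 1 to 5 the list mean was 4.92, 4.88, 5.06, 5.18 and 5.07 for NRF2 targets (4.93 ± 0.08 at 0%), 6.52, 6.69, 6.73, 6.87 and 6.68 for junctions (6.58 ± 0.12) and 3.38, 2.84, 2.96, 2.14 and 2.93 for enteric neurons and glia (3.04 ± 0.29), and replicate 4 was also the lowest of the 21 libraries in smooth muscle markers, at 7.33. The immediate early response list had 9 of 12 positive (adjusted p = 0.0146), with Fosb at 1.51 ± 0.52, Atf3 at 1.35 ± 0.48, Jun at 0.54 ± 0.18 and Klf4 at 0.41 ± 0.11 passing over the list alone. None of the 12 called lists passed with an estimated correlation, and random regroupings of the same libraries called up to 16 lists. The immediate early list mean was 6.06 and 6.22 in 2.5% replicates 1 and 2 and 6.98, 7.37 and 7.12 in replicates 3 to 5, against 5.78 to 6.79 in the other libraries. Tjp1, the scaffold protein of tight junctions, changed by 0.32 ± 0.07 (adjusted p = 0.109) and stood at 151 and 151 CPM in replicates 1 and 2 and at 181, 187 and 176 CPM in replicates 3 to 5.

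Other anchor genes did not pass at 2.5%. Log2 changes were 0.01 for Gclc, the catalytic subunit of glutathione synthesis, -0.33 ± 0.19 for heme oxygenase Hmox1, 0.18 ± 0.29 for the glutathione transferase Gsta1 and 0.11 ± 0.12 for Cyp2c55. The antimicrobial lectins Reg3g and Reg3b stood at 0.21 ± 1.93 and 0.12 ± 1.99, the mucin Muc2 at 0.15 ± 0.38 and Tnf at 0.10 ± 0.63. Il22 had 15 counts over all libraries and Il6 had 165, and both fell under the count filter in every comparison.

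The slope over all 4 diets was tested to ask which genes followed the amount of broccoli powder. Hephl1, a ferroxidase related to hephaestin, rose by 1.14 ± 0.22 in log2 per 1% powder, from 0.62 ± 0.39 CPM (SD, n = 6) at 0% to 3.49 ± 2.72 (n = 5) at 2.5%, but stood at 0.425 ± 0.230 CPM at 0.5% and 0.480 ± 0.342 CPM at 1.0% (n = 5 each), so 7 of the 15 libraries on broccoli lay above the control mean. The phosphatase gene Dusp14 rose by 0.72 ± 0.14 per 1%, the neuropeptide gene Calcb by 0.60 ± 0.12, the membrane fusion gene Stx11 by 0.58 ± 0.12 and the stress-induced phosphatase regulator Ppp1r15a by 0.47 ± 0.09. Spp1 fell, at -0.65 ± 0.14 per 1%. The homeobox gene Pbx4 rose by 0.51 ± 0.11 per 1%, with means of 1.00, 1.27, 1.54 and 2.48 CPM from 0% to 2.5%. Counts of Ppp1r15a (opposite Tulp2) and of Lsmem1 (opposite Gm17056) are uncertain, since strand may not have been used.

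Means at the lower doses stayed near control in several of these genes. From 0% to 2.5%, Calcb was at 2.66, 2.71, 2.36 and 7.16 CPM, Stx11 at 3.30, 3.36, 3.10 and 8.57 CPM, Dusp14 at 1.42, 1.33, 1.78 and 4.55 CPM, and Ppp1r15a at 17.1, 18.6, 17.3 and 38.3 CPM.

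In all, 22 genes had a positive slope and 1 a negative one, and 15 of the 23 were also called at 2.5% against 0%. Adjusted p was 0.0402 for Hephl1, 0.0314 for Dusp14, 0.0325 for Lsmem1 (0.71 ± 0.14 per 1%) and 0.0430 for Calcb, Stx11, Pbx4, Ppp1r15a and Spp1. It was 0.00683 for Ceacam16 (0.95 ± 0.16), Hist1h1e (0.78 ± 0.12), Ly6g6c (0.55 ± 0.08) and Cyp2c23 (0.48 ± 0.08), and 0.0141 for Rasgef1b (0.36 ± 0.06). In 19 of the 22 genes with a positive slope, the 3 highest of all 21 libraries were 2.5% replicates 3, 4 and 5. Dusp14, for example, was at 7.34, 6.94 and 6.02 CPM in these and at 1.46 and 0.98 CPM in replicates 1 and 2.

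**Figure D4:**
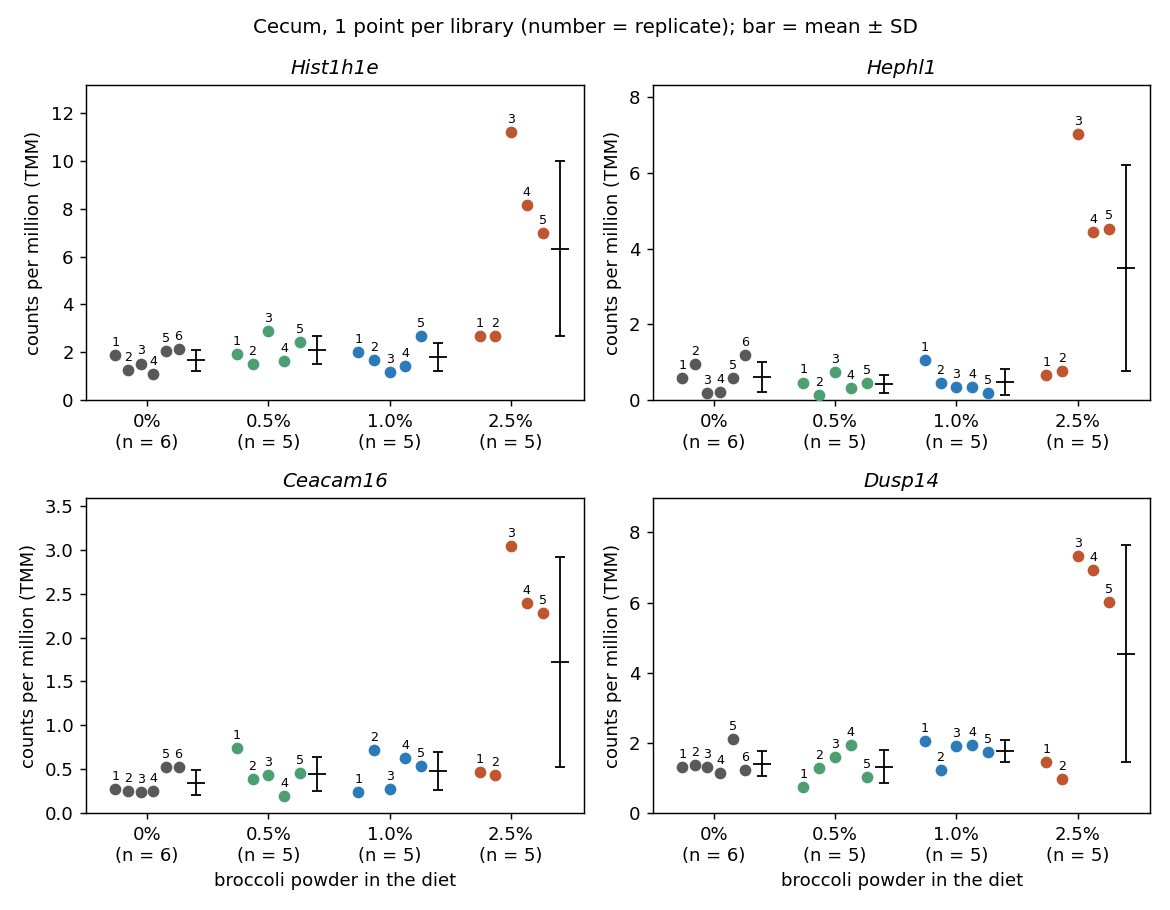
CPM of Hist1h1e, Hephl1, Ceacam16 and Dusp14 in each library, by diet; points are libraries numbered by replicate and bars show the mean ± SD. In each gene 2.5% replicates 3, 4 and 5 were the 3 highest libraries.

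The trend count was 52 by DESeq2 and 24 by voom, and 1146 genes had an unadjusted p under 0.05. With dose as a rank no gene was called, and none was without 2.5% replicate 3 or 4. Without 2.5% replicate 5 or 0% replicate 3 there were 8 calls, without 0.5% replicate 1, 3, 4 or 5, 0% replicate 2, 4, 5 or 6, or 1.0% replicate 3 or 5 there were 10 to 14, without 2.5% replicate 1 there were 56, and without 2.5% replicate 2 there were 46. Ahrr had a slope of 0.35 ± 0.08 (adjusted p = 0.0840), Cyp1a1 of 0.87 ± 0.24 (adjusted p = 0.268) and Tjp1 of 0.12 ± 0.03 (adjusted p = 0.138), and Tiparp of 0.12 and Nqo1 of 0.10 did not pass. Slopes of Cyp1b1 (0.35 ± 0.22), Gclc (-0.02), Hmox1 (-0.14 ± 0.08), Gsta1 (0.09 ± 0.11), Cyp2c55 (0.03), Reg3g (0.22 ± 0.74), Reg3b (0.18 ± 0.77), Muc2 (0.02 ± 0.14) and Tnf (-0.09 ± 0.25) did not pass either.

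As lists, 10 were called in the trend, none of them with an estimated correlation. Targets of the aryl hydrocarbon receptor had 7 of 8 members positive, and Cyp1a1, Ahrr and Tiparp passed over the list alone (adjusted p = 0.000818, and adjusted p = 0.0644 with an estimated correlation). The circadian clock list had 13 of 16 positive, and Nr1d1 and Ciart passed over the list alone (adjusted p = 0.00215, and adjusted p = 0.0644 with an estimated correlation). Colonic transport had 19 of 22 positive (adjusted p = 0.00302, and adjusted p = 0.435 with an estimated correlation), and blood 1 of 5 (adjusted p = 0.00358, and adjusted p = 0.158 with an estimated correlation). Xenobiotic metabolism (20 of 26 positive, adjusted p = 0.00215), tight and adherens junctions (13 of 20, 0.0151), proliferation (19 of 21 positive, 0.00215), cholesterol (19 of 20, 0.000730) and the immediate early list (10 of 12, 0.00188) were higher, and MHC class II (1 of 10, 0.0300) was lower. Each of these 6 had an adjusted p = 0.628 with an estimated correlation.

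At the lowest dose, 0.5% against 0%, 1 gene was called. Arl4d, a small GTPase of the ARF family on chromosome 11 from 101665541 to 101667832 (plus strand), fell to 0.605 of its control level, from 14.9 ± 2.04 CPM (SD, n = 6) to 8.98 ± 1.61 (n = 5). The log2 change was -0.72 ± 0.12 (adjusted p = 0.0386), and 5 of 5 libraries lay below all controls. Arl4d did not follow dose, with 13.8 ± 1.77 CPM at 1.0% and 10.1 ± 0.695 CPM at 2.5%.

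The next values at 0.5% did not pass. Toward higher expression they were Klrb1 (1.42 ± 0.33, adjusted p = 0.554), Cyp2d12 (1.23 ± 0.30), Tppp (0.41 ± 0.10), the monoamine oxidase Maoa (0.35 ± 0.09, adjusted p = 0.557) and Trmt11 (0.41 ± 0.10), and toward lower they were the potassium channel subunit Kcne4 (-0.95 ± 0.18, adjusted p = 0.151), Foxf2 (-0.48 ± 0.11), Rgs2 (-0.49 ± 0.12) and Akna (-0.56 ± 0.13). Of the anchors, Cyp1a1 stood at 0.66 ± 0.63, Ahrr at 0.59 ± 0.20 (adjusted p = 0.675), Gclc at 0.20 ± 0.09, Nqo1 at 0.15 ± 0.11, Tjp1 at 0.15 ± 0.07, Tnf at 0.89 ± 0.62, Reg3g at -1.54 ± 2.05, Muc2 at 0.33 ± 0.38, Cyp2c55 at 0.10 ± 0.12, Hmox1 at -0.05 ± 0.19, Gsta1 at -0.12 ± 0.29, Cyp1b1 at 0.03 ± 0.62, Tiparp at 0.05 ± 0.12 and Reg3b at -1.37 ± 2.10. DESeq2 called 2 genes and voom 1, and 1117 had an unadjusted p under 0.05. The call of Arl4d was lost without 0.5% replicate 1, 2, 4 or 5, 0% replicate 1, 3, 4 or 6, 1.0% replicate 2, 3 or 5, or 2.5% replicate 2, 3, 4 or 5, when no gene was called, and 2 genes were called without 2.5% replicate 1.

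At 0.5%, 5 lists were called. Macrophage and myeloid markers had 0 of 14 members positive and a mean of -0.24 (adjusted p = 0.000528), xenobiotic metabolism 18 of 26 positive (adjusted p = 0.00136), with Cyp2d26, Cyp2s1 and Ces1f passing over the list alone, colonic transport 16 of 22 (adjusted p = 0.0273) and mitochondrially encoded transcripts 12 of 13 (adjusted p = 1.54e-05). Each of these 4 had an adjusted p = 0.735 with an estimated correlation. Enteric neuron and glia markers had 1 of 15 positive (adjusted p = 0.00136, and adjusted p = 0.943 with an estimated correlation). Targets of the aryl hydrocarbon receptor had 8 of 8 positive with a mean of 0.25 and a median of 0.14 and were not called (adjusted p = 0.0660). List means lay beyond all 6 controls in 4 of 5 libraries for xenobiotic metabolism, 3 of 5 for macrophages, 2 of 5 for colonic transport and mitochondrially encoded transcripts, and 1 of 5 for enteric neurons and glia. The macrophage list mean was 3.00 in 0% replicate 5, the control highest in small intestine markers, and 2.32 to 2.69 in the other controls. Without 0.5% replicate 2 there were 10 called lists.

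At 1.0% against 0% no gene was called by edgeR, DESeq2 or voom, and 498 genes had an unadjusted p under 0.05. The values nearest to passing all had an adjusted p of 0.999. They were higher for Rasd2 (0.66 ± 0.17), Rassf9 (0.38 ± 0.10), the hexokinase Hkdc1 (0.51 ± 0.14), the mucin glycosyltransferase B3gnt6 (0.47 ± 0.13) and the enteroendocrine factor Rfx6 (0.82 ± 0.23), and lower for Colgalt2 (-0.70 ± 0.17), the eosinophil lectin Siglecf (-0.66 ± 0.19), Lrrn2 (-0.57 ± 0.16), Tinagl1 (-0.30 ± 0.09) and the hyaluronan synthase Has1 (-1.09 ± 0.32). Cyp1a1 stood at 1.78 ± 0.61, Ahrr at 0.68 ± 0.20, Hmox1 at -0.51 ± 0.19, Nqo1 at 0.26 ± 0.11, Muc2 at -0.08 ± 0.38 and Reg3g at 0.73 ± 1.91. Cyp1b1 stood at 0.41 ± 0.61, Tiparp at -0.06 ± 0.12, Gclc at 0.01 ± 0.09, Gsta1 at 0.17 ± 0.29, Cyp2c55 at 0.07 ± 0.12, Reg3b at 0.77 ± 1.97, Tjp1 at 0.08 ± 0.07 and Tnf at 0.15 ± 0.63.

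As lists, 14 were called at 1.0%. Targets of the aryl hydrocarbon receptor had 6 of 8 members positive with a mean of 0.41 and a median of 0.21 (adjusted p = 0.00745), Cyp1a1 and Ahrr passing over the list alone, and colonic transport had 19 of 22 positive (adjusted p = 0.000652), each with an adjusted p = 0.371 with an estimated correlation. NRF2 targets (22 of 27 positive) and xenobiotic metabolism (23 of 26) were higher and macrophage markers (1 of 14) lower, each at an adjusted p of 0.000652, and each with an adjusted p = 0.488 with an estimated correlation. Xenobiotic metabolism averaged 6.27 and 6.15 in 1.0% replicates 1 and 2, of which replicate 1 is the library highest in small intestine markers, and lay within the control range of 5.76 to 5.96 in replicates 3 to 5. Goblet cell and mucus genes (14 of 20, adjusted p = 0.00270), with Clca1 at 0.50 ± 0.16, proliferation (17 of 21, 0.00145), enteroendocrine (10 of 12, 0.0467) and differentiated epithelium (14 of 16, 0.0316) were higher, and fatty acid synthesis (4 of 16, 0.0275) and mitochondrially encoded transcripts (0 of 13, 0.000739) lower, each with an adjusted p = 0.563 with an estimated correlation. Fibroblast (2 of 11, adjusted p = 0.0275, and adjusted p = 0.724 with an estimated correlation) and enteric neuron and glia markers (1 of 15, adjusted p = 0.0349, and adjusted p = 0.770 with an estimated correlation) were lower. Adipose markers were called lower, with a mean of -1.03 in log2 CPM, although 7 of 11 had a positive fold change in the gene test (adjusted p = 0.0330, and adjusted p = 0.770 with an estimated correlation). Their list mean was 1.91 and 0.60 in 1.0% replicates 2 and 3 and 5.92, 3.36 and 5.45 in replicates 1, 4 and 5. Fatty acid synthesis split the same way, with a list mean of 5.45, 5.38 and 5.49 in replicates 2 to 4 and 6.41 and 5.95 in replicates 1 and 5, against 5.90 ± 0.22 at 0%. List means lay beyond all 6 controls in 4 of 5 libraries at 1.0% for the receptor targets, 3 of 5 for colonic transport, fatty acid synthesis and adipose markers, 2 of 5 for NRF2 targets, xenobiotic metabolism, enteroendocrine cells and differentiated epithelium, 0 of 5 for goblet cells and 1 of 5 for the other 5 called lists. For macrophages 0% replicate 5 stood at 3.00 and the other controls at 2.32 to 2.69, while 1.0% replicate 1 stood at 2.80 and replicates 2 to 5 at 2.22 to 2.39. Without 0% replicate 6 there were 7 called lists, and without 0% replicate 4 or 1.0% replicate 5 there were 9.

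The mean of the 3 broccoli diets against 0% asked for changes shared by the doses. No gene was called by edgeR or voom, DESeq2 called 7, and 1030 had an unadjusted p under 0.05. The values nearest to passing were higher for Edn3 (0.39 ± 0.08, adjusted p = 0.234), Gnpda2 (0.45 ± 0.10), the carboxylesterase Ces1f (0.41 ± 0.09), Ahrr (0.76 ± 0.17, adjusted p = 0.251) and Maoa (0.29 ± 0.07, adjusted p = 0.466). Ahrr averaged 3.31 ± 0.69 CPM at 0.5%, 3.51 ± 0.74 at 1.0% and 4.42 ± 1.06 at 2.5% (SD, n = 5 each), and 14 of 15 libraries lay above all 6 controls. The lower values were Zfp395 (-0.36 ± 0.07, adjusted p = 0.234), Arl4d (-0.46 ± 0.09), Colgalt2 (-0.63 ± 0.13), Cntfr (-0.71 ± 0.17) and Prss22 (-4.20 ± 0.90, adjusted p = 0.354), which rested on 34.0 CPM in 0% replicate 5. Cyp1a1 stood at 1.57 ± 0.53 (adjusted p = 0.670) and Tjp1 at 0.18 ± 0.06. The remaining anchors did not pass either, with Cyp1b1 at 0.42 ± 0.50, Tiparp at 0.10 ± 0.10, Nqo1 at 0.23 ± 0.09, Gclc at 0.08 ± 0.07, Hmox1 at -0.30 ± 0.15, Gsta1 at 0.08 ± 0.23, Cyp2c55 at 0.09 ± 0.10, Reg3g at -0.20 ± 1.53, Reg3b at -0.16 ± 1.58, Muc2 at 0.13 ± 0.31 and Tnf at 0.38 ± 0.51.

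Over the 3 diets together, 9 lists were called, none with an estimated correlation. Targets of the aryl hydrocarbon receptor had 8 of 8 members positive with a mean of 0.41 and a median of 0.17, and Cyp1a1, Ahrr and Nqo1 passed over the list alone (adjusted p = 0.000709, and adjusted p = 0.125 with an estimated correlation). Colonic transport had 19 of 22 positive (adjusted p = 0.000354, and adjusted p = 0.263 with an estimated correlation) and xenobiotic metabolism 19 of 26 (adjusted p = 3.12e-05, and adjusted p = 0.465 with an estimated correlation). NRF2 targets had 20 of 27 (adjusted p = 0.00414) and macrophage markers 1 of 14 positive (adjusted p = 0.000455), each with an adjusted p = 0.508 with an estimated correlation. Goblet cell (16 of 20, adjusted p = 0.00944), proliferation (18 of 21, 0.0108), cholesterol (19 of 20, 0.0199) and enteric neuron and glia genes (1 of 15, 0.00153) each had an adjusted p = 0.780 with an estimated correlation. List means lay beyond all 6 controls in 11 of 15 libraries for the receptor targets, 9 for xenobiotic metabolism, 7 for colonic transport, 6 for cholesterol, 5 for NRF2 targets, 4 for macrophages, 3 for proliferation and for enteric neurons and glia, and 2 for goblet cells. The control mean for macrophages includes 0% replicate 5 at 3.00, against 2.32 to 2.69 in the other controls.

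Differences among the 4 diets were called for Arl4d, Hist1h1e and Pax8 (adjusted p = 0.0271 each) and the predicted gene Gm19410 (0.0448). Below these came Spp1 (0.0597), Edn3 and Adprm (0.0741), and Cyp2c23, Hephl1 and Ceacam16 (0.0774). DESeq2 called 65 genes and voom 3, and 1003 had an unadjusted p under 0.05. No gene was called without 0.5% replicate 1, 0% replicate 3, 4 or 6, 1.0% replicate 3 or 4, or 2.5% replicate 3, 4 or 5, 1 without 1.0% replicate 5, 35 without 2.5% replicate 1 and 21 without 2.5% replicate 2.

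Among the 3 broccoli diets edgeR called no gene, DESeq2 37 and voom 3, and 921 had an unadjusted p under 0.05. The lowest p belonged to Hist1h1e, Gm19410, Spp1, Pax8, Hephl1 and Calcb (adjusted p = 0.136), the chemokine Cxcl16 (0.138), the p53 regulator Mdm2 (0.143), and Arl4d and Cyp2c23 (0.149). Cxcl16 was at 7.64 and 9.93 CPM in 2.5% replicates 1 and 2 and at 22.03, 26.3 and 27.3 CPM in replicates 3 to 5. Without 2.5% replicate 1 there were 21 calls and without 2.5% replicate 2 there were 18.

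Fold changes of the doses were compared across genes, which are not independent replicates. Pearson's r was 0.455 between 0.5% and 1.0%, 0.563 between 0.5% and 2.5%, and 0.507 between 1.0% and 2.5%. Leaving out libraries in turn (jackknife) gave an SE of 0.178, 0.149 and 0.165. Simulated unchanged groups that shared 6 simulated controls gave 0.470, 0.451 and 0.452. These simulations hold no correlation between genes and no differences in tissue make-up such as that of 0% replicate 5, so they may not match the real libraries. With the real controls split so that none was shared the observed r was -0.057, 0.071 and 0.000. The covariance less its simulated value was -0.00251, 0.00886 and 0.00274. No called gene was shared between the doses, where independent lists would share 0.000128 lower genes between 0.5% and 2.5%. With 1 call at 0.5%, 0 at 1.0% and 17 at 2.5% hardly any could be shared, so this says nothing about effects common to the doses.

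Tissue make-up was compared with 48 exact permutation tests over 16 lists of other cell types and RNA quality, and none passed the adjustment. The smallest p these splits allow is 0.00216, which alone among 48 tests would adjust to 0.104, so a single list could not have passed. Blood transcripts at 2.5% had the lowest exact p (0.0390, adjusted 0.748), with a difference of -0.36.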

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

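The tests of small intestinal tissue in the libraries, of 1 library behind the aryl hydrocarbon receptor targets and of diet behind the small intestine list were chosen after the result was seen, and the others were not.

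The 17 genes called at 2.5% against 0% were weighed against the make-up of the libraries, an acute stress response and the time of day. With the small intestine and adipose list means as covariates all 17 kept the greater part of their log2 change, and 13 were still called among 15, as the median size of the change went from 0.91 to 0.91 and its SE from 0.17 to 0.17. The small intestine list itself stood at 1.71 ± 1.69 at 0% and 1.89 ± 1.21 at 2.5%, so its covariate could hardly move these changes. That near balance counts against small intestinal tissue as the whole cause, and the fit adds little to it. With the immediate early list mean as a covariate no gene was called, and the median size went from 0.91 to 0.75 at an SE of 0.17. The size fell in Hist1h1e (1.94 ± 0.32 to 1.48), Ceacam16 (2.32 ± 0.46 to 1.76), Ly6g6c (1.33 ± 0.24 to 1.09), Rasgef1b (0.91 ± 0.17 to 0.75), Rhou (0.60 ± 0.12 to 0.50) and Adprm (0.55 ± 0.10 to 0.44). Smaller falls were seen in others, such as Hmga1b (0.59 ± 0.12 to 0.50) and Pax8 (0.72 ± 0.11 to 0.65). Acute stress or handling may have a share in these genes, but several falls were no larger than the SE. The immediate early list was also highest in 2.5% replicates 3, 4 and 5, so this covariate cannot tell stress from another trait of these 3. In Ahrr (1.01 ± 0.20 to 1.06 ± 0.21), Crym (0.54 ± 0.11 to 0.56 ± 0.12) and Zfp395 (-0.48 ± 0.09 to -0.49 ± 0.10) the size did not fall and the SE rose. With the circadian clock list mean as a covariate none was called either, as the median size fell from 0.91 to 0.80 and the median SE rose from 0.17 to 0.19. The size fell in Ahrr (1.01 to 0.85), Rasgef1b (0.91 to 0.80) and Crym (0.54 to 0.48) but not in Spp1 (-1.75 to -1.76) or Hist1h1e (1.94 to 1.98). All 17 kept the greater part of their change with either list, so neither list mean accounted for the whole change. Time of day is not decided by this, because the clock list holds genes that a shift of phase may move in opposite directions. An acute stress response that the immediate early list follows poorly is not excluded either. A response to the diet also stays open. In 100 splits of the 11 libraries only 1, the real one, gave 17 calls, and the highest other gave 10. This argues against chance for that count but does not exclude it, since the split tests were not adjusted for their number. No gene was called in a fit of the 2 groups only, or without 2.5% replicate 3, 4 or 5. The splits also cannot tell a response to the diet from a condition shared by those libraries.

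Targets of the aryl hydrocarbon receptor averaged a log2 change of 0.56 at 2.5%, with a median of 0.28 over the 8 measured members. The mean was drawn up by a few of them, with Cyp1a1 at 2.27 ± 0.61 and Ahrr at 1.01 ± 0.20, both genes of low counts. The mean was 0.60 with the small intestine and adipose covariates. The small intestine list itself stood at 1.71 ± 1.69 at 0% and 1.89 ± 1.21 at 2.5%, so its covariate could hardly move the mean. That near balance counts against small intestinal tissue, and the fit adds little to it. Leaving out 1 of the 11 libraries at a time gave at least 0.47, the lowest without 2.5% replicate 4, which counts against a single library. Activation of the receptor by the diet may therefore be considered as a hypothesis. It stays unproven, since the list had an adjusted p of 0.0877 with an estimated correlation and Ahrr was called in 10 of 34 alternatives, although its log2 change stayed between 0.85 and 1.12 in all 34.

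Markers of the small intestine and Paneth cells were high in 6 libraries spread over the 4 diets. The 8 measured members had a median pairwise Pearson r of 0.83 over 21 libraries centred within each diet, which mostly restates that the list mean differed between libraries. Distal small intestine taken with the cecum is a candidate explanation that stays open, with Apoa1 at 323 CPM, Slc10a2 at 337 CPM and Defa24 at 47.3 CPM in 1.0% replicate 1, while Slc10a2 (57.3 to 99.3 CPM) and Alpi (37.6 to 60.3 CPM) were also present in the 5 libraries at 0% that are low in the list, so 2 of the 8 are no specific markers. Diet would have to move the group means, and the lowest exact permutation p over the doses was 0.678, with a largest difference of 0.44 beside an SD of up to 2.07.

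Other results of the splits were these. Chance cannot be excluded for the 1 call at 0.5%, where the highest other split gave 1 and 6 of 100 gave as many. At 1.0%, over all diets and among the 3 broccoli diets no gene was called, so all 100 splits had to reach as many and say nothing about chance, and the highest others gave 9, 96 and 4 calls. Few splits, the real one included, reached the 4 calls among the 4 diets (3 of 100, highest other 22) and the 23 of the trend (2 of 100, highest other 98). Chance is not excluded for either, since some regroupings gave more calls than the diets did and the split tests were not adjusted for their number. The splits with 22 and 98 calls, several times the real counts of 4 and 23, point to a structure of the samples. The first principal component of log2 CPM, with 17.7% of the variance, had a Pearson r of 0.975 with the small intestine list over the 21 libraries, and 2.5% replicates 3, 4 and 5 shared the 3 highest values in 186 genes, but the libraries these splits put together were not compared with either. For the lists, chance cannot be excluded in any comparison. Real counts of 5, 14, 12, 9 and 10 at 0.5%, 1.0%, 2.5%, over all diets and in the trend were reached by 80, 14, 16, 54 and 31 of 100 splits, with highest others of 16, 17, 16, 19 and 18.

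In 20 of 296 groups of libraries tested, 1 library lay far from the rest of its diet, where about 1 in 20 groups would be picked out by chance. In 0% replicate 5 the list means in log2 CPM were 4.24 for antimicrobial genes (others 1.92 to 2.67), 2.37 for cytokines (0.79 to 1.13), 5.28 for intestinal stem cells (4.09 to 4.40) and 5.09 for the small intestine (0.46 to 1.42). In the same library Reg3g was at 67.9 CPM (others 0.0824 to 0.978), Muc2 at 3777 CPM (678 to 1290), Cyp2c55 at 1813 CPM (3107 to 3537), Cyp1b1 at 3.74 CPM (0.494 to 1.01) and Dusp14 at 2.10 CPM (1.16 to 1.37). In 1.0% replicate 1 the list means were 5.20 for stem cells, 2.67 for MHC class II, 2.80 for macrophages and 5.51 for the small intestine, and Muc2 was at 1973 CPM (others 1145 to 1262). Interferon-stimulated genes averaged 3.84 in 1.0% replicate 2 (others 2.89 to 3.03), and differentiated epithelium 8.88 in 2.5% replicate 4 (others 8.68 to 8.72). Ahrr was low in 0% replicate 6 at 1.19 CPM (others 2.21 to 2.69), Lsmem1 in 0.5% replicate 4 at 0.677 CPM (others 0.992 to 1.15) and Pbx4 in 1.0% replicate 4 at 0.966 CPM (others 1.56 to 1.85). Gclc was high in 2.5% replicate 5 at 259 CPM (others 240.6 to 245.0).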

How the results depend on the processing

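The settings with small intestine and adipose covariates and without the 6 libraries high in small intestine markers were chosen after the data were seen, and so were their tests. The 6 include 2.5% replicates 1 and 2, so that setting compares 2.5% replicates 3, 4 and 5 with the controls and is no check of those calls. No paired analysis was possible because the replicate numbers are in accession order and pair no libraries. Where a count moved by more than 1.5 times, the cause was not tested. Fits of fewer libraries hold less information, but this would not account for counts that rose, such as 56 genes at 2.5% without 2.5% replicate 1. RLE scaling, no filter and the filter of 1 CPM in 5 libraries moved no count that far, and no called value of a named gene changed sign. Of 475 values of the named genes called at 2.5% 247 stayed called, of 441 in the trend 272, of 132 among the 4 diets 77, and of 34 for Arl4d at 0.5% 14. Values not called in the report became called 4 times at 0.5%, 5 at 2.5%, 7 over all diets, 2 in the trend, 34 among the 4 diets and 36 among the 3 broccoli diets.

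Genes called at 0.5% (1 in the report) were 0 with a surrogate variable, in a fit of 2 groups only, without the robust option, without animals numbered above 70 and without the 6 libraries, 2 by DESeq2, and 4 with smooth muscle and B cell covariates. At 2.5% (17) they were 6 with a surrogate variable, 0 in a fit of 2 groups, 77 by DESeq2, 7 with library totals, 9 by voom, 10 without the robust option, 5 without animals numbered above 70 and 121 without the 6 libraries. Over all diets (0) DESeq2 gave 7 and the small intestine and adipose covariates 3. In the trend (23) a surrogate variable gave 9, DESeq2 52, dose as a rank 0, smooth muscle and B cell covariates 10, small intestine and adipose covariates 15, omission of animals above 70 13, and omission of the 6 libraries 101. Among the 4 diets (4) the counts were 0 with a surrogate variable, 65 by DESeq2, 11 with smooth muscle and B cell covariates, 7 without the robust option, 0 without animals above 70 and 86 without the 6 libraries. Among the 3 broccoli diets (0) they were 37 by DESeq2, 3 by voom, 2 with smooth muscle and B cell covariates and 86 without the 6 libraries.

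Called lists fell to 0 in all 5 comparisons with an estimated correlation and by the mixed test of fry. By the directional test of fry they were 0 at 0.5% and 1.0%, 1 at 2.5%, 1 over all diets and 2 in the trend, which were targets of the aryl hydrocarbon receptor in each and the circadian clock in the trend. At 0.5% (5) they were 8 with library totals, 8 with smooth muscle and B cell covariates and 3 without the 6 libraries, and over all diets (9) they were 15 with a surrogate variable. The correlation of fold changes became -0.057 between 0.5% and 1.0%, 0.071 between 0.5% and 2.5% and 0.000 between 1.0% and 2.5% with the controls split, which removes the shared controls.

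Leaving out each library in turn gave 0 to 2 genes at 0.5%, 0 at 1.0%, 0 to 56 at 2.5%, 0 over all diets, 0 to 56 in the trend, 0 to 35 among the 4 diets and 0 to 21 among the 3 broccoli diets. For lists the ranges were 4 to 10, 7 to 14, 8 to 15, 6 to 12 and 9 to 13 at 0.5%, 1.0%, 2.5%, over all diets and in the trend. The counts of 0 genes at 1.0% and over all diets compare with 498 and 1030 genes at an unadjusted p under 0.05, by edgeR. The called gene most often kept at 2.5% was Pax8, in 30 of 34 settings, followed by Edn3 and Spp1 in 29, Hist1h1e in 26, Adprm in 24 and Zfp395 in 18. With library totals the median log2 change of all genes was -0.09 at 0.5% and -0.07 at 2.5%. Depth limits genes near 1 CPM, such as Spp1, Ceacam16 and Cyp1a1, more than the others.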

Other observations

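The test of a condition shared by 3 libraries at 2.5% was chosen after the pattern was seen, and the rule for reading the clock test was tightened after its value was seen.

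Defence, immune and metabolic gene groups not described so far were not called at 2.5% by camera. Antimicrobial genes had 8 of 18 members positive (adjusted p = 0.721), although Ido1, which degrades tryptophan, passed over the list alone at 0.83 ± 0.24. Interferon-stimulated genes had 16 of 23 positive (adjusted p = 0.106), cytokines and chemokines 5 of 14 (0.461), and goblet cell and mucus genes 15 of 20 (0.0535). B cells and lymphoid follicles had 10 of 14 positive (0.233), with the complement receptor Cr2 at 0.50 ± 0.14, plasma cells 3 of 9 (0.692), with the plasma cell regulator Prdm1 at 0.68 ± 0.19, T cells 4 of 12 (0.903) and macrophages 1 of 14 (0.103). Fatty acid oxidation had 11 of 24 positive (0.993), yet Pdk4, which restrains glucose oxidation, stood at 1.29 ± 0.35 and the fatty acid binding protein Fabp2 at 0.44 ± 0.13, both passing over the list alone. Fatty acid synthesis had 9 of 16 positive (0.990).

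Of the remaining cell type and stress lists at 2.5%, stem cells had 6 of 11 positive (0.246), enteroendocrine cells 7 of 12 (0.170), tuft cells 3 of 8 (0.242), differentiated epithelium 9 of 16 (0.222), smooth muscle 2 of 13 (0.203), fibroblasts 3 of 11 (0.222), endothelium 5 of 10 (0.469) and mesothelium 2 of 3 (0.461), with the adjusted p in parentheses. Adipose tissue had 2 of 11 positive with a mean of -0.58 (0.220), small intestine 3 of 8 (0.461), heat shock 3 of 10 (0.277), the unfolded protein response 2 of 13 (0.242) and mitochondrially encoded transcripts 11 of 13 (0.0980).

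A first hypothesis is that 2.5% replicates 3, 4 and 5 share a condition that replicates 1 and 2 lack. These 3 were the 3 highest of all 21 libraries in 186 of the tested genes, where the highest of the other sets of 3 libraries of 1 diet reached 60 and the median of the 50 sets was 10.5. Of the genes called higher at 2.5%, 11 of 15 had these 3 highest, and of those called higher in the trend 19 of 22. Ppp1r15a was at 45.96, 62.7 and 46.8 CPM in them and at 16.8 and 19.1 CPM in replicates 1 and 2, and Mdm2 at 137, 157 and 159 against 83.4 and 89.6 CPM. Tissue make-up split the same way, since replicates 1 and 2 were high in the small intestine list (3.24 and 3.17, against 1.10, 1.22 and 0.72 in replicates 3 to 5) and in the fibroblast list (4.91 and 4.92, against 4.07, 3.97 and 4.58). A low content of small intestinal tissue was not particular to replicates 3 to 5, since the 0% libraries other than replicate 5 were similarly low in that list (0.46 to 1.42). With the small intestine and adipose covariates the median size of the 17 called changes stayed at 0.91. The small intestine list mean was 1.71 at 0% and 1.89 at 2.5%, so its covariate could hardly move that size, and the fit adds little on this point. The labels name no shared day or batch, and no cage. They do number these 3 mice 44, 45 and 46, in a row, and replicates 1 and 2 40 and 42. A difference that follows the animal number can therefore not be set aside. The condition may be another difference in the tissue sampled, a day of collection, handling or a response of some mice to the diet, and the 5 libraries do not separate these. Spp1, Cyp2c23 and Ahrr lay beyond all controls in 5 of 5 libraries at 2.5%, but so did Hist1h1e, Ly6g6c and Rasgef1b, so this does not set those genes apart from the pattern. The mean of the aryl hydrocarbon receptor target list did not split that way. It was 3.09 and 3.17 in 2.5% replicates 1 and 2 and 3.15, 3.48 and 2.59 in replicates 3 to 5, against 2.53 ± 0.17 at 0%.

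A second hypothesis is a shift of clock phase at 2.5%. The test looked for opposite movement, which a later or earlier phase may but need not give. It set a first set of 5 genes (Arntl, Clock, Npas2, Nfil3 and Cry1) against a second set of 9 that includes Dbp, Nr1d1 and Ciart. The second set had a median log2 change of 0.50 and the first -0.02, a difference of 0.52. Before it was tightened, the rule asked for opposite signs and a minimum difference, and these values met it. The first median lay within its SE of 0.16, however, so its sign is uncertain, and a phase shift could not be told from higher expression of the second set alone.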
